A study of Mus musculus with 8 samples.

How the data were processed

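RNA from sorted mouse mammary gland cells was hybridised to Illumina mouse bead arrays, with 8 arrays in 4 groups of 2. The groups were FDG-high and FDG-low cells of Axl+/LacZ glands and of AxlLacZ/LacZ glands. Group and replicate number were taken from the sample titles. Each sample was a pool of glands from several animals of one genotype, per the labels. The labels do not say whether replicates of a group came from separate pools, so p-values measure the spread between these samples, which may in part be technical. The array positions in the labels place all 8 arrays on the same chip, so no chip or slide could act as a batch between groups. The design text names a whole-genome array type, whereas the probe number and the array positions match a smaller format with more arrays per chip, and the values were used as they stand.

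The deposited values are linear probe intensities, per the value table itself, for 25697 probes on each array. The design text states that the study worked with log2 quantile normalized values, but the deposited intensities had neither been log transformed nor brought to a common distribution, and their scanner settings, bead summary and background handling are not given in the sources used here. The test design had assumed log2 values. Intensities were therefore background corrected with the normexp model of limma 3.58.1 in R 4.3.3 (offset 50), quantile normalized across the 8 arrays and log2 transformed. Fold changes are on this offset scale, which understates the change of dim genes.

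Probes were named from the platform's annotation table, in which 23978 probes had 1 gene symbol, 0 had several and 1719 had none. Of the named probes, 23962 matched a mouse gene of the GRCm38.p6 reference by gene identifier, and the update changed 0 symbols. The reference was used for names and for gene order only. The brightest probe by its mean over all arrays stood for each of 16593 genes, 4777 of which had more than 1 probe. Among the genes named in the text, Wnt7b, Rbm47, Mbp, Prr15l, Atp2a3 and Pik3r1 had another probe above background with the opposite sign in at least 1 comparison, and no such probe passed an unadjusted p of 0.05. No detection p-values or negative control probes were used here. The background level of an array was set to the 95th percentile of 1326 probes for odorant, vomeronasal and trace amine receptors. A gene counted as above background on an array if any of its probes was. Where a gene was below background on both arrays of a group, the difference is given as at least a number of fold. That bound is the mean of the brighter group over the mean, across the dim arrays, of the higher of the probe's own value and the lowest value above background.

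The 5 contrasts were fitted in a single limma model with a coefficient per group and no covariate (4 residual and 2.4 prior degrees of freedom): FDG-high against FDG-low in each genotype, homozygous against heterozygous in each gate, and the interaction of gate and genotype. Tests were moderated and two-sided, and p-values were adjusted over all genes with the Benjamini-Hochberg method (threshold 0.05). The rank product, which the design text names for the genotype comparison in FDG-high cells, was coded anew over the 4 pairs of arrays with 100 permutations, a one-sided permutation p under 0.01 per direction and at least 1.5-fold. It treats genes as exchangeable within an array. Molecular signatures used by the study were not used here.

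Before the data were examined, 29 gene lists were fixed. They held markers of basal, luminal progenitor and hormone-sensing luminal cells, of all epithelial cells, and of fibroblasts, adipocytes, pericytes, endothelium, myeloid and lymphoid cells, Schwann cells, skeletal muscle, epidermis and erythrocytes. The others covered mesenchymal transition, milk proteins, proliferation, immediate-early genes, TAM receptors and ligands together with Pik3r1, Socs1 and Socs3 (the TAM list), interferon response, inflammatory cytokines, lysosome, Wnt and Notch signalling, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein response, ribosomal proteins, apoptosis, and the chromosomal neighbourhood of Axl. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a contrast. Camera compares a list with all other genes, and fry tests whether the genes of a list move one way.

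The genes to be named were also fixed by a rule. For each gate comparison and for the genotype comparison in FDG-high cells it took the TAM list, the 10 largest log2 differences per direction among genes past the threshold with separated groups, and up to 4 members of each list with the largest absolute log2 difference. Where fewer than 3 genes passed in a direction, the 5 with the largest moderated statistic stood in. The FDG-low genotype comparison and the interaction contributed 5 per direction, and the rank product the 5 smallest p per direction. Genes without an informative name were passed over.

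Data were simulated for the FDG-high genotype comparison with the real means of 16593 genes and 200 genes given a known change. Spreads were drawn at random from the distribution fitted by limma, and genes varied independently. The real spread of each gene and the correlation between genes were thus not reproduced. In these data limma called 61% of genes changed by log2 1 and 91% of those changed by log2 2, with 7 unchanged genes called. The rank product called 96% and 100% of them, with 368 unchanged genes called. Gene counts were recomputed with other normalizations, a filter on dim genes, the mean of all probes, an intensity trend in the variance, the replicate number as a factor, only the groups compared (not for the interaction), and each array left out in turn. For the lists, the rank product and the correlation of gate effects, the alternatives were other normalizations, the filter on dim genes and left-out arrays. The replicate number was used for the lists and the rank product as well, an estimated correlation for the lists, and limma and adjusted p-values for the rank product. The number of arrays limits the precision of every comparison.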

Results

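The study measured gene expression in mammary gland cells of nulliparous mice, 16 weeks old, that carried a lacZ insertion in Axl on 1 allele (Axl+/LacZ, heterozygous) or on both (AxlLacZ/LacZ, homozygous). Axl encodes a receptor tyrosine kinase of the TAM family, and the insertion both reports on and disrupts the gene. FDG, a substrate that fluoresces once cleaved by the lacZ product, was used to sort viable cells negative for CD45, CD31 and CD11b. The 5% brightest cells formed the FDG-high group and the 65% dimmest the FDG-low group. Each of the 4 groups had 2 arrays. Median intensities lay between 115.7 and 126.7 units, maxima between 13157 and 19322 units, and between 48.1% and 55.5% of probes were above the background level. Normalized log2 intensities are given below as mean ± SD with n = 2 arrays, and log2 differences with their standard error from limma.

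Axl, measured by 1 probe, was compared with the genotype labels, and its level does not settle the gate labels. Its normalized log2 intensity was 9.01 ± 0.17 in heterozygous FDG-high cells and 8.21 ± 0.33 in heterozygous FDG-low cells. In homozygous cells it was 6.24 ± 0.23 in the FDG-high gate and 6.32 ± 0.11 in the FDG-low gate, near background, with 1 and 2 of the 2 arrays above it. The homozygous to heterozygous difference was -2.77 ± 0.20 among FDG-high cells (limma, adjusted p = 0.080) and -1.90 ± 0.20 among FDG-low cells (adjusted p = 0.0065). The latter call was lost without the first or the second homozygous FDG-low array (adjusted p = 0.066 and 0.051). Where the probe lies relative to the insertion is not given in the sources used here. Between the heterozygous gates, the difference in Axl was 0.80 ± 0.20 in favour of FDG-high cells and did not pass the threshold (adjusted p = 0.24).

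**Figure D1:**
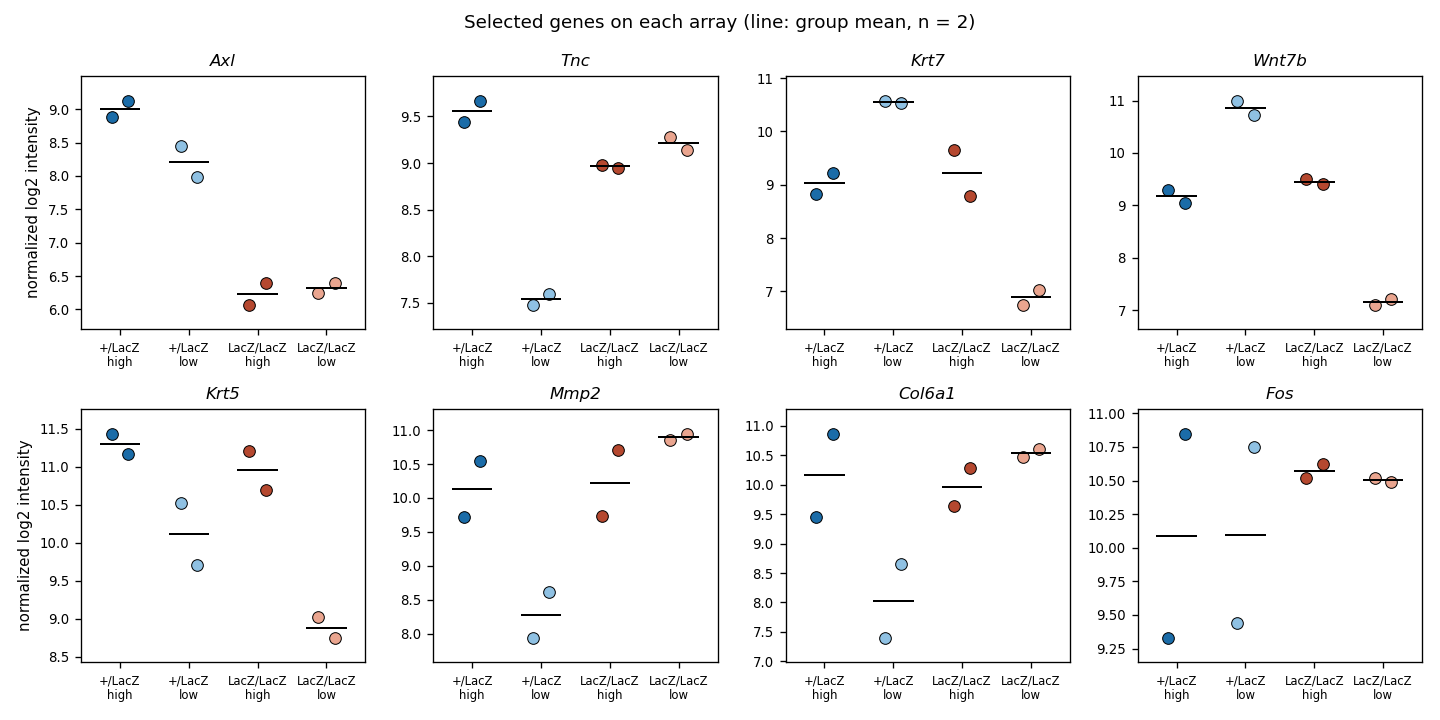
Normalized log2 intensity of 8 genes on each array (points), by genotype and gate, with the mean of the 2 arrays of a group as a line. Axl was lowest on the 4 homozygous arrays, and Krt7 and Wnt7b were lowest on the homozygous FDG-low arrays, at means of 6.89 and 7.15.

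The comparison of FDG-high with FDG-low cells in heterozygous glands asked what sets cells with an active Axl locus apart. Few single genes passed, while the fibroblast list was shifted upwards and the epithelial and luminal lists downwards in FDG-high cells. Tnc, which encodes the matrix protein tenascin C, was the only gene past the threshold, at 9.55 ± 0.16 against 7.54 ± 0.09, a log2 difference of 2.01 ± 0.11 or 4.02-fold (limma, adjusted p = 0.019). Of the genes that did not pass, the highest statistics in favour of FDG-high cells belonged to the metalloproteinase Mmp12 (at least 2.67-fold, adjusted p = 0.056), the adhesion molecule Vcam1 (1.02 ± 0.11), Nfatc4 (1.12 ± 0.13), Aebp1 (1.13 ± 0.14) and Bnc2 (1.36 ± 0.17). In the other direction these were Wnt7b (-1.69 ± 0.14), the water channel Aqp5 (-1.48 ± 0.13), Tmc4 (-1.38 ± 0.12), Vill (-1.23 ± 0.11) and Smagp (-1.70 ± 0.17). These values rest on the brightest probe, and another probe gave 0.17 for Tnc, 0.71 for Bnc2, 0.01 for Wnt7b and -0.19 for Vill. For Smagp and Aqp5, with 2 of 3 and 1 of 2 probes above background, it was 0.08 and -0.05.

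All 20 measured fibroblast markers had a positive log2 difference in this comparison, with a median of 1.56 (camera, adjusted p = 7.1e-16). None passed over all genes, and 15 were higher adjusted over the list alone. Col5a1 (2.64 ± 0.72), Col3a1 (2.17 ± 0.79), Col6a1 (2.13 ± 0.56) and Pdgfra (2.01 ± 0.62) had the largest differences. Genes of mesenchymal transition had a median of 0.96 (adjusted p = 4.6e-07), with 8 of 17 higher adjusted over the list alone, including Mmp3 at 1.99 ± 0.38 and Zeb2 at 1.68 ± 0.45. Basal markers had a median of 0.66 (adjusted p = 2.9e-06), and Mylk, a kinase of the contractile apparatus, differed by 1.38 ± 0.31, with 0 of 19 higher adjusted over the list alone. The TAM list had a median of 0.32 (adjusted p = 0.0038), in which Pros1, a ligand of TAM receptors, differed by 1.39 ± 0.20, Mertk by 0.27 ± 0.17, Pik3r1 by 0.40 ± 0.18, Socs3 by 0.36 ± 0.32, Gas6 by 0.12 ± 0.38 and Socs1 by -0.06 ± 0.15, while Tyro3 was below background in both gates. Adjusted over the list alone, 2 of its 8 genes were higher. The list includes Axl itself, whose reporter defined the gates, so its call is in part given by the sort. Interferon response, lysosome and unfolded protein response lists had smaller positive medians of 0.36, 0.27 and 0.17 (adjusted p = 3.2e-04, 5.0e-04 and 9.7e-04), with Cxcl10 at 1.06 ± 0.25 and cathepsin K, Ctsk, at 1.88 ± 0.47. With an estimated correlation none of these 7 calls held (adjusted p = 0.30 for fibroblast and mesenchymal genes, 0.36 for basal genes, 0.29 for the TAM list, 0.45 for interferon genes, 0.36 for the lysosome and 0.26 for the unfolded protein response).

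Epithelial markers moved the other way, with a negative log2 difference for 18 of 19 and a median of -0.93 (camera, adjusted p = 2.8e-13). Adjusted over the list alone, 13 were lower, and the claudin Cldn3 (-1.80 ± 0.33) and the keratins Krt7 (-1.54 ± 0.29) and Krt19 (-1.31 ± 0.30) had the largest differences. Luminal progenitor markers had a median of -0.86 (adjusted p = 2.6e-07), with 12 of 18 lower adjusted over the list alone, led by the lactoferrin gene Ltf (-1.59 ± 0.32) and Csn3 (-1.50 ± 0.41). The medians of the hormone-sensing luminal, milk protein and ribosomal protein lists were -0.29, -0.10 and -0.14 (adjusted p = 3.3e-04, 0.0038 and 0.0043). With an estimated correlation these calls were lost as well (adjusted p = 0.29 for epithelial, luminal progenitor and milk protein genes, 0.26 for hormone-sensing genes and 0.45 for ribosomal genes). At an unadjusted p under 0.05, 1701 genes differed between the gates where chance would give 830. When any array other than the first heterozygous FDG-high one was left out, 0 genes passed, whereas 6 passed without that array. With the replicate block, that is the replicate number as a factor, 0 genes passed. This factor was common to both genotypes, whereas replicate differences correlated between the gates in heterozygous (0.40) but not in homozygous glands (0.01). It is therefore not a test of pairing within heterozygous glands. With the mean of all probes, Tnc differed by 0.87 (adjusted p = 0.12, with a range of 0.013 to 0.23 over all alternatives).

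In homozygous glands the same gate comparison ran the other way for most epithelial genes, as FDG-high cells had the higher levels. Of 65 genes past the threshold, 43 were higher and 22 lower in FDG-high cells. Krt23 rose by 2.91 ± 0.16, or 7.54-fold, from 6.48 ± 0.08 to 9.39 ± 0.20 (limma, adjusted p = 0.0064). Krt7 (2.33 ± 0.29), Wnt7b (2.30 ± 0.14), the transcription factor Tfap2b (2.24 ± 0.14), the RNA-binding protein gene Rbm47 (2.11 ± 0.19), the membrane protease St14 (2.11 ± 0.19), Nme7 (2.07 ± 0.22), the glycosylation enzyme Galnt3 (2.01 ± 0.21), the desmosomal gene Pkp3 (1.99 ± 0.11) and the epithelial splicing factor Esrp1 (1.88 ± 0.20) followed. For Wnt7b, Rbm47 and Nme7 another probe gave a value near 0. The genes with the largest falls were the beta globin Hbb-bt (-2.04 ± 0.20), Chchd10 (-1.74 ± 0.22), the eosinophil granule protein gene Prg2 (-1.67 ± 0.16), Arid3a (-1.62 ± 0.13), Jarid2 (-1.37 ± 0.14), the globin Hbb-b2 (at least 2.01-fold lower), Ggt5 (-1.25 ± 0.16), the neuropeptide gene Gal (at least 2.06-fold lower), Olfr456 (-1.18 ± 0.11) and Ccl21b (-1.18 ± 0.09).

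All 19 epithelial markers had a positive log2 difference, with a median of 1.31 (camera, adjusted p = 2.7e-15). Of these 5 rose over all genes and 13 adjusted over the list alone. Basal markers had a median of 1.23 (adjusted p = 1.4e-10), with 2 of 19 risen over all genes and 11 adjusted over the list alone, and Krt5 at 2.07 ± 0.30 and Mylk at 2.05 ± 0.31 just outside the threshold. Luminal progenitor and hormone-sensing luminal lists had medians of 0.44 and 0.39 (adjusted p = 9.4e-07 and 1.3e-06), each with 1 member past the threshold over all genes. The growth factor gene Ptn rose by 1.56 ± 0.10 in the latter. Ribosomal protein, cholesterol synthesis and glycolysis lists had medians of 0.19, 0.24 and 0.18 (adjusted p = 4.3e-05, 0.026 and 0.0023). Fibroblast (median -0.48), mesenchymal transition (-0.50), interferon (-0.53), lysosome (-0.15), immediate-early (-0.22) and erythrocyte (-0.21) lists were shifted downwards (adjusted p = 0.015, 0.0088, 5.6e-04, 0.025, 0.046 and 1.5e-04). Only the erythrocyte list among them had members past the threshold, which were the 2 globins. Every list call was lost with an estimated correlation, where the adjusted p was 0.29 for epithelial, 0.31 for basal and luminal progenitor, 0.15 for hormone-sensing, 0.73 for fibroblast and 0.19 for erythrocyte genes. For the other 7 called lists it lay between 0.31 and 0.76, and fry called 3 lists. Members of the TAM list did not pass, at -0.08 ± 0.20 for Axl, -0.45 ± 0.17 for Mertk, -0.39 ± 0.38 for Gas6, -0.21 ± 0.20 for Pros1, -0.04 ± 0.18 for Pik3r1, -0.17 ± 0.15 for Socs1 and -0.22 ± 0.32 for Socs3, and Tyro3 was dim.

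The homozygous result rested on few arrays. Without the first homozygous FDG-high array, or without either homozygous FDG-low array, 0 genes passed, without either heterozygous FDG-low array 19 did, and without the second homozygous FDG-high array 138 did. A fit to the 4 homozygous arrays alone called 0 genes, and the limma model of all arrays gave 2144 genes at an unadjusted p under 0.05 where chance would give 830. The excess of higher genes depended on the scaling and on the background correction. Median centring gave 170 higher and 23 lower. Quantile normalization without background correction gave 21 and 22, and log2 of the value plus 16, also without it, gave 18 and 22. The list calls fell from 13 to 7 without the first homozygous FDG-high array.

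**Figure D2:**
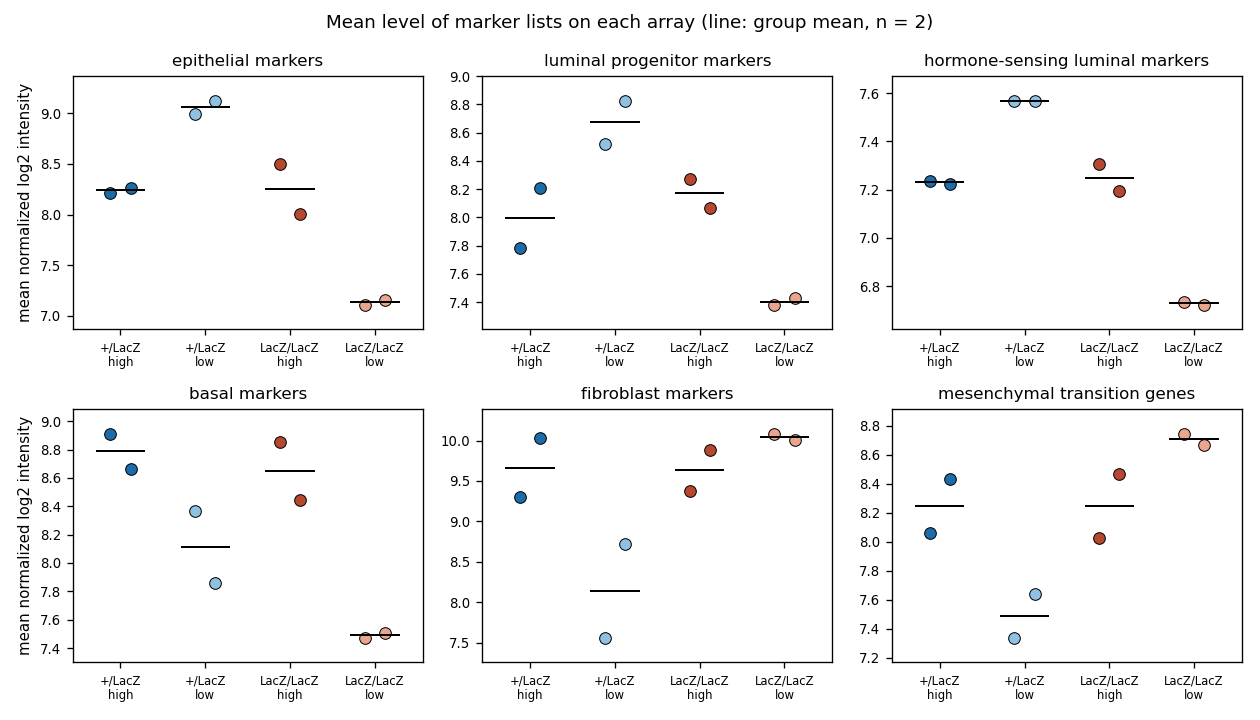
Mean normalized log2 intensity of 6 marker lists on each array (points), by genotype and gate, with group means as lines. Epithelial markers averaged 8.24 and 8.25 in the FDG-high groups, 9.06 in heterozygous and 7.13 in homozygous FDG-low cells, while fibroblast markers averaged 9.67, 9.63, 8.14 and 10.05 in the same order.

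Whether the gate difference depended on genotype was tested directly. The interaction passed the threshold for 135 genes, 96 with a higher and 39 with a lower gate difference in homozygous glands, and in 132 of them the gate difference had opposite signs in the genotypes. Wnt7b (interaction log2 3.99 ± 0.19), Krt7 (3.87 ± 0.41), Nme7 (3.72 ± 0.30), Ltf (3.50 ± 0.45) and Rbm47 (3.42 ± 0.26) had the largest positive values. The collagenase Mmp13 (-2.86 ± 0.39), Dennd2a (-2.68 ± 0.30), Il17rd (-2.46 ± 0.34), Gpr176 (-2.46 ± 0.31) and Mmp12 (-2.41 ± 0.16) had the largest negative ones. These values rest on the brightest probe: another probe gave -0.01 for Wnt7b, 0.02 for Nme7, 0.63 for Ltf and -0.33 for Mmp13, and over all alternatives Nme7 fell to 1.32 and Rbm47 to 1.10. The interaction of the epithelial list had a median of 1.83 (camera, adjusted p = 1.5e-19, with 7 of 19 members past the threshold) and that of the fibroblast list a median of -1.85 (adjusted p = 2.2e-11, with 0 of 20). With an estimated correlation these adjusted p-values were 0.25 and 0.30. Across 16593 genes the gate differences of the genotypes, which share no array, had a Pearson correlation of -0.31 and a Spearman correlation of -0.19, and genes are not independent replicates. Among genes with an unadjusted p under 0.05 in both, 445 had opposite and 120 the same sign, where independent lists would share 110 of each.

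The number of interaction calls changed with single arrays. It was 0 without either homozygous FDG-low array, 1 without either heterozygous FDG-low array, 13 without the second heterozygous FDG-high array, 44 without the first and 328 without the second homozygous FDG-high array. Without the first heterozygous FDG-high array 66 calls were higher and 80 lower, and under median centring 161 of 183 were higher. The correlation moved to -0.14 without the first and to -0.40 without the second homozygous FDG-high array.

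**Figure D3:**
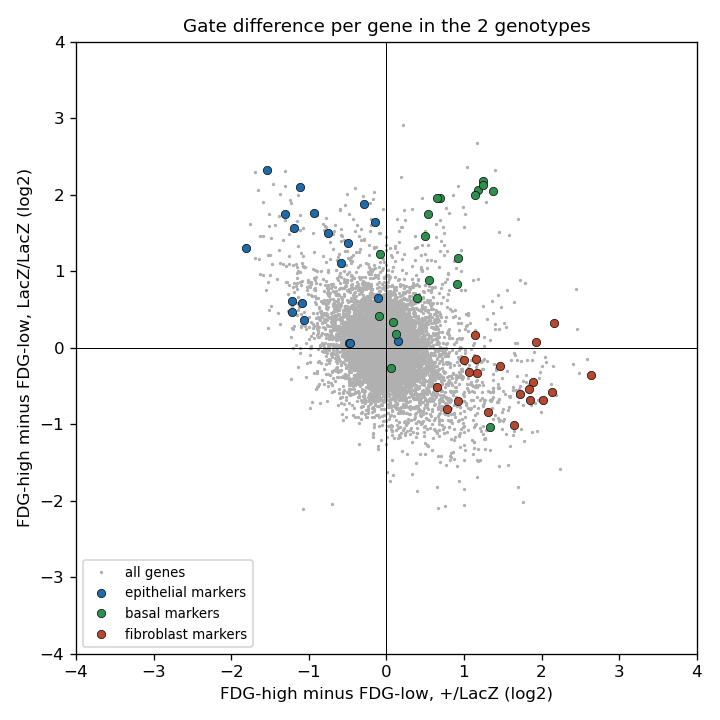
Log2 difference of FDG-high minus FDG-low cells per gene in heterozygous (horizontal axis) and homozygous glands (vertical axis), with epithelial, basal and fibroblast markers in colour. Epithelial markers lie mostly at upper left, fibroblast markers at lower right and basal markers at upper right, and the correlation over all genes was -0.31.

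The comparison of homozygous with heterozygous FDG-high cells, the genotype test of the study, asked how cells with an active Axl locus change when the gene is disrupted. Apart from Axl itself, the groups were close. Across genes, their arrays correlated at a mean of 0.970, against 0.963 within each group. No gene passed the threshold in limma, and Axl had the smallest adjusted p at 0.080. At an unadjusted p under 0.05 there were 639 genes, below the 830 that chance would give. After Axl, the lowest statistics belonged to Asb2 (-1.27 ± 0.20), the mitochondrial ribosomal gene Mrps12 (-0.89 ± 0.15), Prr15l (-0.67 ± 0.11) and Rusf1 (-0.76 ± 0.13), and the highest to the carnitine carrier Slc25a20 (0.61 ± 0.10), Bcl2l14 (at least 1.43-fold), Arf2 (0.63 ± 0.12), S100a9 (at least 1.02-fold) and Zswim4 (0.67 ± 0.13). Other members of the TAM list were at 0.01 ± 0.17 for Mertk, 0.38 ± 0.38 for Gas6, 0.13 ± 0.20 for Pros1, -0.12 ± 0.18 for Pik3r1, 0.04 ± 0.15 for Socs1 and 0.40 ± 0.32 for Socs3.

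None of the 29 lists was called in this comparison. The epithelial list had a median of 0.07, the basal list of -0.19, the luminal progenitor list of 0.13, the hormone-sensing list of -0.02 and the fibroblast list of -0.05 (camera, adjusted p = 0.80, 0.36, 0.14, 0.77 and 0.99). The epithelial, hormone-sensing and fibroblast lists each had a median of the opposite sign to the camera direction, and the TAM list had a median of 0.03 but a mean of -0.24. With an estimated correlation the smallest adjusted p was 0.84, and with fry 0.95. The interferon list had a median of -0.18 and the cholesterol list of -0.14 (adjusted p = 0.14 for both). When a single FDG-high array was left out, 7 lists were called without the second heterozygous array, 6 without the first and 7 without the second homozygous array. Axl passed the threshold among genes above the median brightness (adjusted p = 0.0059) and with an intensity trend in the variance (adjusted p = 0.0037), and over all alternatives its adjusted p lay between 0.0037 and 1.

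The rank product at the study's thresholds gave 202 genes for this comparison, 95 higher and 107 lower in homozygous cells. Axl had the smallest permutation p, 6.0e-07, the smallest the permutations can give, with a 6.82-fold lower level. Asb2 (2.41-fold), the calcium pump gene Atp2a3 (2.15-fold), the kinase gene Dyrk1b (2.11-fold) and the atypical chemokine receptor gene Ackr4 (2.04-fold) were the next lower ones. The protocadherin Pcdh10 (2.44-fold), the nucleotide receptor P2ry6 (2.43-fold), Arhgap20 (2.05-fold), Cdk5r1 (1.95-fold) and Nanos1 (1.91-fold) led the higher ones. Another probe gave a log2 difference of -0.06 for Pcdh10, 0.03 for Atp2a3 and -0.13 for Ackr4. For Dyrk1b, with 1 of 2 probes above background, it was -0.11. A permutation p under 0.01 would arise by chance for 166 genes per direction, before the fold threshold. After Benjamini-Hochberg adjustment only Axl remained. Of the 202 genes, 46 had a limma p under 0.01. Under median centring, an alternative added after the data had been seen, 131 of 189 calls were higher. Without the first or the second heterozygous array 386 and 365 genes were called, mostly higher (283 and 266), and without the first or the second homozygous array 395 and 369, mostly lower (307 and 264).

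Among FDG-low cells the genotypes differed far more. In limma 1396 genes passed, 628 higher and 768 lower in homozygous cells, and across genes their arrays correlated at a mean of 0.888, the lowest of any pair of groups. The secreted matrix protein gene Thbs2 rose by 3.63 ± 0.45, or 12.4-fold (adjusted p = 0.0095), followed by Dipk1c (3.58 ± 0.53), the sterol hydroxylase Ch25h (3.57 ± 0.52), Rgcc (3.07 ± 0.45) and the mesenchymal transcription factor Twist2 (7.99-fold, adjusted p = 0.0089). The connexin Gjb2 (-3.75 ± 0.66), Wnt7b (-3.71 ± 0.14), Wfdc12 (at least 11.4-fold lower), Krt7 (-3.67 ± 0.29) and Cytip (-3.55 ± 0.70) had the largest falls. These values rest on the brightest probe, and another probe gave -1.60 for Gjb2 and -0.09 for Wnt7b.

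Of 19 epithelial markers 17 fell and 0 rose in homozygous FDG-low cells, with a median of -1.94 (camera, adjusted p = 1.4e-18). St14 fell by 3.42, Cldn3 by 2.92 and the transcription factor gene Ehf by 2.75. Luminal progenitor markers had 10 of 18 members lower (median -1.39, adjusted p = 1.0e-06), including Ltf at -3.28 ± 0.32 and Tspan8 at -2.61 ± 0.30. Hormone-sensing markers had 7 of 16 lower (median -0.55, adjusted p = 1.2e-06) and basal markers 3 of 19 (median -0.85, adjusted p = 9.0e-04), including the smooth muscle actin gene Acta2 at -1.62 ± 0.15. Milk protein genes had 4 lower and 1 higher of 16 (median -0.13, adjusted p = 0.049), and the ribosomal list had 1 of 20 lower (median -0.36, adjusted p = 2.1e-05). Fibroblast markers had 9 of 20 higher and 0 lower (median 1.83, adjusted p = 7.6e-12), with the gelatinase gene Mmp2 at 2.62 ± 0.41 and Col6a1 at 2.51 ± 0.56, and mesenchymal transition genes had 9 of 17 higher (median 1.57, adjusted p = 1.1e-06). Interferon genes had 4 of 24 higher (median 0.73, adjusted p = 2.7e-04), among them Cxcl10 at 1.84 ± 0.25. The lysosome, erythrocyte, immediate-early and unfolded protein response lists had medians of 0.24, 0.20, 0.55 and 0.28 (adjusted p = 0.0017, 0.016, 0.020 and 0.017), with Ctsk at 2.98 ± 0.47 and Hbb-bt at 1.41 ± 0.20. None of the 13 calls held with an estimated correlation. The adjusted p was then 0.32 for epithelial, 0.37 for luminal progenitor, fibroblast and mesenchymal, 0.15 for hormone-sensing and 0.44 for basal and interferon genes, and between 0.33 and 0.67 for the other 6 lists. Fry called 7 lists.

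Endothelial, pericyte, myeloid and lymphoid markers had medians of 0.06, 0.24, -0.05 and -0.02 in the same comparison and were not called (camera, adjusted p = 0.51, 0.094, 0.31 and 0.65). Adipocyte, Schwann cell, skeletal muscle and epidermal markers had medians of 0.08, 0.05, 0.02 and 0.01 (adjusted p = 0.95, 0.96, 0.58 and 0.78). Only 6 of 20 myeloid, 3 of 17 lymphoid and 2 of 13 skeletal muscle markers were above background on at least 2 arrays, so their medians say little. Proliferation, inflammatory cytokine, Wnt and Notch, and apoptosis genes had medians of 0.06, 0.39, 0.01 and 0.09 (adjusted p = 0.83, 0.057, 0.96 and 0.96), and the neighbours of Axl had a median of -0.11 (adjusted p = 0.29). The mean had the opposite sign to the median for Schwann cell, epidermal, proliferation, Wnt and Notch, and apoptosis genes. The TAM list had a median of 0.53 (adjusted p = 0.080), in which Pros1 rose by 1.73. Across all 5 comparisons 16 lists were called at least once and 13 never, with a smallest camera adjusted p of 0.057 among the latter. Without the first or the second homozygous FDG-low array 121 and 157 genes passed, and without the first or the second heterozygous FDG-low array 547 and 570 did. Without normalization or background correction 847 genes passed.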

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

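The predictions for exchanged gates, normalization, cell composition, the window shares around Axl and the pairing of replicates were written after the results they concern had been seen. Those on the sign of neighbours in FDG-low cells and on immediate-early genes were written before.

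A difference between the genotypes in the same gate comparison, tested as an interaction, marked 135 genes in all. Among lists it marked those of epithelial (median interaction log2 1.83), luminal progenitor (1.52), basal (0.68), hormone-sensing luminal (0.61), ribosomal protein (0.38) and milk protein genes (0.17) as having the higher difference of FDG-high minus FDG-low cells in homozygous glands. Fibroblast (-1.85), mesenchymal transition (-1.38), interferon (-0.92), TAM (-0.54), lysosome (-0.40), unfolded protein response (-0.33) and erythrocyte lists (-0.31) had the lower difference. The TAM list includes Axl, the disrupted gene, so its call is in part given by the genotypes. None of these 13 list calls held with an estimated correlation, where the smallest adjusted p was 0.12, and fry called 5.

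Of the genes named in the text, 40 passed the interaction test in limma, at adjusted p-values from 0.0073 to 0.049. Members of the epithelial and luminal lists with a positive interaction log2 were Krt7 (3.87), Ltf (3.50), St14 (3.22), Krt19 (3.06), Aldh1a3 (2.66), Lcn2 (2.43), Esrp1 (2.17), Ptn (1.89), Mboat1 (1.86) and Prss8 (1.83). Itga6 (1.31) belonged to the basal list. Others were Wnt7b (3.99), Nme7 (3.72), Rbm47 (3.42), Smagp (2.87), Krt23 (2.70), Tmc4 (2.67), Aqp5 (2.57), Galnt3 (2.52), Pkp3 (2.29), Mbp (2.11), Tfap2b (2.05), Ccl5 (1.97), Vill (1.37) and Bcl2l14 (1.32). A negative value was found for Mmp13 (-2.86), Dennd2a (-2.68), Gpr176 (-2.46), Il17rd (-2.46), Mmp12 (-2.41), Tnc (-2.25), Jarid2 (-2.23), Bnc2 (-2.15), Prg2 (-1.76), Ggt5 (-1.75), Arid3a (-1.63), Nfatc4 (-1.62), Ccl21b (-1.33), Olfr456 (-1.27) and Vcam1 (-1.23). The number of calls was 0 without either homozygous FDG-low array, 1 without either heterozygous FDG-low array, 146 without the first (66 higher, 80 lower) and 13 without the second heterozygous FDG-high array, 44 without the first and 328 without the second homozygous FDG-high array.

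Homozygous FDG-low arrays differed from heterozygous ones at 1396 genes. Between-array normalization as the whole cause was argued against by 847 calls without normalization or background correction, a comparison that says nothing on array brightness. An exchange of gate labels within homozygous glands remained open, with values on both sides. The gate effects would then correlate at 0.31, and 4 of 5 called cell type lists would take the heterozygous sign, but basal markers would not. Across genes, arrays labelled homozygous FDG-high correlated at 0.968 to 0.973 with heterozygous FDG-high and at 0.927 to 0.961 with heterozygous FDG-low arrays, which goes against an exchange. Those labelled homozygous FDG-low were also closer to heterozygous FDG-high arrays (mean 0.938) than to heterozygous FDG-low ones (0.888). Fewer epithelial and more fibroblast cells in the homozygous FDG-low sort may account for the list changes but remained open: 0 of 45 called members went against that direction, which restates the list results. Endothelial markers (median 0.06) and adipocyte markers (0.08) were not called. This says little, as the sort removed CD31-positive cells and only 8 of 16 adipocyte markers were above background. Disruption of Axl is the biological candidate and could not be separated from the composition of the sort, and without the first or the second homozygous FDG-low array the count was 121 or 157.

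The rank product called 8 genes, Axl left out, within 100 measured genes of Axl on either side, where windows elsewhere had a mean of 2.5. A strain-derived segment around the targeted gene may contribute but remained open, because the share of windows with as many calls was 0.014 and 0.0054 for 100 and 150 genes on either side but 0.44 and 0.35 for 25 and 50. A difference of genotype present in both gates also remained open, as 5 of the 8 had the same sign in FDG-low cells, against 130 of 201 among all calls. Mrps12 (-0.89 and -0.80) and Apoe (0.72 and 2.73) also passed in FDG-low cells with the same sign. An effect of Axl on its neighbours was not separable from these.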

How the results depend on the processing

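All alternatives named as added below were chosen after seeing the data. Signs were compared for named genes only, each in the comparison it was named for. None of these that was past the threshold in the main fit or in the alternative changed sign. No list called in the main fit changed direction, and the correlation kept its sign. Among named genes and lists not called in the main fit, 98 values of genes and 114 of lists changed sign or direction. The balance of higher and lower calls did reverse. The homozygous gate went from 43 and 22 to 18 and 22 with log2 of the value plus 16 and no background correction. The balance of the interaction and of the rank product also turned when single arrays were left out. No scaling moved the median of all genes by over 0.1 on the log2 scale. Quantile normalization and median centring bring the arrays to like medians, so for them this was nearly given in advance. Without normalization the largest median was 0.071, for the genotypes in FDG-high cells. The arrays had between 48.1% and 55.5% of probes above background, which limits statements on dim genes. Of the values for named genes past the threshold, 1206 kept their side of it and 552 lost it. For lists these were 610 and 101. A lone array of a group was assumed to vary like the other groups, and unless stated the cause of a change was not tested.

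In this section, log2 of the value plus 16 was taken without background correction. The alternative without normalization, which was added, also left out background correction. For the heterozygous gate, 1 gene became 0 with only the compared groups in the fit, with the mean of all probes, with the replicate block, and in the added alternative without normalization. It became 2 with median centring and with an intensity trend, 5 among genes above the median brightness, where fewer genes were tested, and 0 to 6 when single arrays were left out. For the homozygous gate, 65 genes became 0 with only the compared groups, 193 with median centring, 162 among brighter genes and with an intensity trend, 40 with log2 of the value plus 16, 52 with the replicate block, 0 to 138 without single arrays, and in the added alternatives 43 without background correction and 135 without normalization. For the genotypes in FDG-high cells, 0 became 1 among brighter genes and with an intensity trend, and was 0 with the replicate block and without any array. In FDG-low cells 1396 became 847 without normalization, 1497 with the replicate block and 121 to 1473 without single arrays. The interaction moved from 135 to 321 among brighter genes, 316 with an intensity trend, 81 with log2 of the value plus 16, 117 with the replicate block and 0 to 328 without single arrays.

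Called lists became 0 with an estimated correlation in both gate comparisons, in the FDG-low genotype comparison and in the interaction. With the replicate block they were 13 and 13 for the gates, 0 and 15 for the genotypes and 16 for the interaction. In the homozygous gate they ranged from 7 to 14 without single arrays, and for the genotypes in FDG-high cells from 0 to 7, with 2 under median centring, both higher, and 2 without normalization, both lower. The rank product gave 46 genes with limma in its place, 96 among brighter genes, 1 after Benjamini-Hochberg adjustment, 62 without background correction (added), 203 over same-numbered pairs (replicate block), and 365 to 395 without single arrays, where fewer pairs enter. The correlation of gate effects ranged from -0.40 to -0.14 without single arrays.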

Other observations

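The gene families and the weighing of single-pool replicates were chosen for testing after the FDG-low comparison and the replicate differences had been seen. Only the prediction on immediate-early genes was written before its result.

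Gene families, which share members with the fixed lists, were also counted between genotypes in FDG-low cells. Matrix metalloproteinases had 7 of 15 members higher in homozygous cells, including Mmp3 (2.68 ± 0.38), Mmp2 (2.62 ± 0.41), Mmp12 (2.56 ± 0.11) and Mmp13 (2.43 ± 0.28). Collagens had 7 of 31 higher, among them Col6a2 (2.86 ± 0.58), with Col4a6 lower, and laminins had 3 of 8, among them Lamc3 (2.63 ± 0.33). Claudins had 6 of 15 lower, led by Cldn3 (-2.92 ± 0.33), and keratins 5 of 23, including Krt23 (-3.23 ± 0.16). Fisher's exact test over 20 tests and a background of 11781 genes gave adjusted p = 1.0e-04, 0.0067, 0.023, 0.0023 and 0.042 for these 5 families, and genes are not independent. Members of the fixed lists made up 4 of the 5 lower keratins, 3 of the 6 lower claudins, 3 of the 7 higher metalloproteinases and 1 collagen. Without any list member, metalloproteinases (4 of 12 higher), collagens (6 of 25) and laminins (3 of 8) still passed, at adjusted p = 0.016, 0.016 and 0.031 in the exact test, while claudins (3 of 12 lower) and keratins (1 of 15) did not (adjusted p = 0.14 and 1).

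Chemokines had 7 of 33 members higher, including Ccl7 (2.33 ± 0.52) and Ccl2 (2.06 ± 0.44), and 4 lower, including Ccl5 (-2.02 ± 0.21). For the higher ones the adjusted p was 0.0075 in Fisher's exact test and 0.23 without list members. The higher members outside the lists were Ccl21a (1.23 ± 0.14), Ccl21b (1.41 ± 0.09) and Ccl21c (1.24 ± 0.20). Fisher's test counted these as separate genes, although they may not vary independently. IGF-binding proteins, none of them in a list, had 3 of 6 higher and Igfbp3 lower (adjusted p = 0.011). Integrins with 4 of 22 lower, Hox genes with 4 of 29 higher and Wnt genes with 1 of 14 lower did not pass (adjusted p = 0.13, 0.15 and 1). Hoxc6 (2.55 ± 0.26) and Hoxc10 (2.49 ± 0.43) were the largest of the Hox genes past the threshold.

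Heterozygous replicates deviated together across the gates. Across genes, the replicate differences of the heterozygous gates correlated at 0.40, against 0.01 in homozygous glands, so a shared cell pool per replicate number may apply to heterozygous glands but remained open. Immediate-early genes induced by dissociation may be part of it: their median difference of replicate 2 minus 1 was 0.46 in FDG-high and 0.59 in FDG-low heterozygous cells, outside the central range of 10000 random lists (-0.20 to 0.16 and -0.17 to 0.20), and 0.00 and 0.02 in homozygous cells. Fibroblast markers also averaged higher on replicate 2 than on replicate 1 of heterozygous cells. Their means were 10.035 against 9.297 in FDG-high and 8.721 against 7.560 in FDG-low cells. In homozygous cells they were 9.886 against 9.376 and 10.011 against 10.087. Only the immediate-early list was set against random lists, so dissociation is not singled out. The random lists were matched on brightness but not on shared variation, while the immediate-early list had an estimated inter-gene correlation of 0.57. Genes that vary together leave such a range more easily, so the comparison cannot decide on dissociation. Without the immediate-early list the correlation of the heterozygous replicate differences was 0.39. Its 23 members are few among 16593 genes, so the correlation could hardly have fallen. That value decides nothing on genes outside the list that respond alike. No biological explanation was tested.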
